A study of Homo sapiens with 111 samples.

How the data were processed

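RNA was sequenced from frozen kidney tissue of organ donors, cadaveric kidneys, normal tissue adjacent to a tumor, and tumors. Per the labels' protocols, stranded mRNA libraries with poly(A) selection were sequenced as read pairs. Per the submitters' processing notes, the reads were quantified with Salmon. The deposited values are estimated counts per Ensembl gene, as whole numbers without scaling, and the table's totals differ between libraries. The Salmon version, the genome build, the transcript annotation and the step from transcripts to genes are not given in the sources used here.

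The table held 34270 rows, of which 1 was cut off and left out. All 34269 others matched Ensembl IDs of the reference annotation (release 29, GRCh38), which also gave symbols and coordinates. They covered 18175 of its 19951 protein-coding genes (91.1%). The rows end at the one cut off, and the highest complete ID was ENSG00000238223. Genes with higher IDs, HBB and PECAM1 among them, were therefore not analysed and are missing from all total counts. Genes of the Y chromosome and XIST (391) were left out of every test, which left 33878 genes. The counts of libraries with the same specimen number were summed, from 111 libraries to 91 specimens. In fits with the library class as a term they were summed per specimen and class, without a term for the specimen. The total count per library sets the precision, and a count of 3 was used as the floor of a single library. A group mean pools many libraries, but no fold is given against a mean below the floor at the group's median depth.

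Comparisons, tests, thresholds, gene lists, the rule for named genes and part of the alternatives were fixed before the data were examined. Genes with enough counts by filterByExpr were tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F-test on TMM-normalised counts, with Benjamini-Hochberg adjustment. A call needs an adjusted p below 0.05 and an absolute log2 fold change of at least 1. Comparisons among non-tumor tissues used the 3 non-tumor groups in one fit, and those with tumors used all 4 groups. Library letters were compared with the specimen number as a block. Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, with a preset inter-gene correlation of 0.01 and with an estimated one. Of 43 lists fixed, 41 held enough genes after realignment. Permutation tests used 100000 resamples and were two-sided.

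Genes named in each comparison were of 3 kinds. The first were up to 5 genes with the largest rise and 5 with the largest fall, among those with an adjusted p below 0.05, at least 5 CPM in the higher group and at least 80% of one group's specimens beyond the median of the other. The second were 2 members of each of up to 10 lists with the smallest camera p. The third were genes fixed in advance: HAVCR1, LCN2, FOS, EGR1, HSPA1A, IL6, UMOD, SLC34A1, AQP2, NPHS1, CD163, MT-CO1, CA9, NDUFA4L2, VEGFA, SLC22A6, SLC22A2 and CYP4A11, of which CA9 had too few counts to be tested between non-tumor tissues. Immunoglobulin, T cell receptor and HLA genes, and genes with common germline deletions, were not named under the first.

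Displaced rows were found after the data were examined, by comparing libraries B and C with libraries A at row offsets of up to 15. Each library was then classed as displaced or not by its own rows at these offsets. The offsets form 18 segments, 15 of them with an offset. Counts in displaced libraries were moved to the row of their own gene ("realigned"), and 15069 rows were left out as unsure, 14207 of them with too few counts to check and 749 because the summed counts of the 2 kinds of library differed. A first, looser version of this row check left out 723 rows. It was tightened after its calls had been seen. Realignment, the library class term, the removal of the GC trend, and taking gene values and lists from the realigned counts were all chosen after the data were examined. The other alternatives chosen then are named where their values are given.

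The row step, the gene test in 3 comparisons and camera with the preset correlation were tested on simulated data. Camera with an estimated correlation, the class term, the removal of the GC trend and the spread test were not. With offsets simulated in part of the rows, the row step gave the right offset to 99.99% of 13738 expressed rows, those without an offset included. The simulated offsets did not reach the largest ones found in the data. With no offset simulated at all, 0 rows were given one. Recovery of changed genes was counted by an adjusted p below 0.05 alone, without the fold threshold of a call. For normal adjacent minus organ donor (13938 genes) the gene test recovered 64.2% of 1.5-fold, 95.5% of 2-fold and 100% of 4-fold changes. For cadaveric minus normal adjacent (13935 genes) it recovered 56.7%, 90.9% and 100%, and for tumor minus normal adjacent (14321 genes) 50.8%, 80.6% and 98.5%. Of the genes with such an adjusted p, 4%, 5.3% and 5% were unchanged genes in these 3 simulations. The 1.5-fold changes had a median absolute log2 fold change of 0.55, 0.61 and 0.6, below the threshold of a call. These rates therefore describe the adjusted p and not the calls. With 1 list raised 2-fold, camera with the preset correlation found that list each time, and also called 2, 2 and 4 of 38 lists that share no gene with it.

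Alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling (2 libraries with an upper quartile of 0 were left out of the latter), no filter on low counts, letter A only, all libraries as separate samples, other groups in the fit, 2 technical factors from the letters, and other gene sets. Figures were drawn with matplotlib 3.10.9, and sequence copies of mitochondrial genes were searched with BLAST 2.17.0.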

Results

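Messenger RNA was measured by sequencing in 111 libraries of frozen human kidney tissue from 91 specimens. The specimens came from 4 sources: 20 from organ donors, 20 from cadaveric kidneys, 26 from normal tissue adjacent to a kidney tumor, and 25 from kidney tumors. In all, 10 specimens carried 3 libraries each, lettered A, B and C in the labels. The libraries of a specimen were summed, so that n counts specimens except where stated. The deposited values were estimated counts per gene, and 33878 genes were used. Total counts per library ran from 3691903 to 38850349 in organ donors (median 19505564.5), from 170 to 10114866 in cadaveric tissue (median 2164624), from 167486 to 12937245 in normal adjacent tissue (median 3660219) and from 1137 to 14616029 in tumors (median 4518139). Fewer than 500000 counts were found in 3 cadaveric, 2 normal adjacent and 2 tumor libraries. At the median depth, a count of 3 corresponded to 0.15 CPM (counts scaled to library size) in organ donors, 1.39 in cadaveric, 0.82 in normal adjacent and 0.66 in tumor libraries. These floors apply to a single library of median depth and cover counting error only.

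In part of the libraries, the counts of many genes stood on the row of another gene. The medians that follow leave out 1 of the 10 lettered specimens, whose library A did not match its libraries B and C. In the A libraries of the other 9, MT-CO1 (ENSG00000198804), a mitochondrially encoded subunit of cytochrome c oxidase, had a median of 54768 CPM. The preceding row, LRIG2, had 16.1 CPM. In libraries B and C of the same specimens, MT-CO1 had 81.2 CPM and LRIG2 55524 CPM. Another 10 mitochondrial genes showed the same exchange with a nearby row, while MT-ND4L had 3511 CPM in libraries A and 3381 CPM in libraries B and C. Of the 34269 rows, 20970 (61.2%) were displaced in this way, in 37 libraries, and 74 libraries were not displaced. The displaced libraries were all 20 libraries with the letters B or C and 17 libraries of organ donors without a letter. On displaced rows, 18 ribosomal protein genes had a median of 13 CPM in the displaced libraries as deposited and 452.5 CPM once the counts were moved back, against 587.7 CPM in the 67 other libraries with at least 500000 counts.

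**Figure D1:**
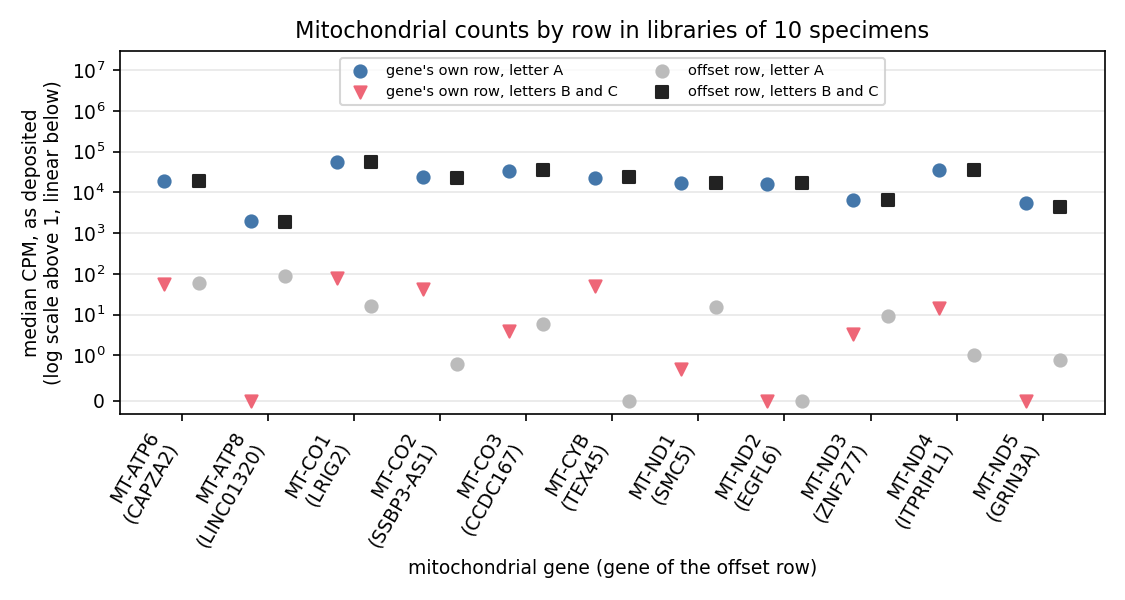
Median CPM as deposited (vertical axis, logarithmic above 1) of 11 mitochondrial genes on their own row and on the row that held their counts in libraries B and C, for the 9 lettered specimens whose libraries matched. The 10 specimens of the title include 1 that is not in these medians. In libraries A the high values, such as 54768 CPM of MT-CO1, stand on the gene's own row, and in libraries B and C they stand on the other row.

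The displaced libraries were not spread evenly over the sources, since 17 of the 20 organ donor specimens were represented only by displaced libraries. Counts of called genes are therefore given for the table as deposited and for counts moved back to their own gene ("realigned"), and gene values, gene lists and named genes are given from the realigned counts, with levels in CPM on normalised library sizes. This choice was made after the data were examined. A gene was called when its adjusted p (edgeR quasi-likelihood test, Benjamini-Hochberg) was below 0.05 and its fold change at least 2. Where the library class (displaced or not) is a term, libraries were summed per specimen and class. Each lettered specimen then entered once in each class, with no term for the specimen. All p-values with the class term therefore treat such repeat libraries as independent samples.

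**Figure D2:**
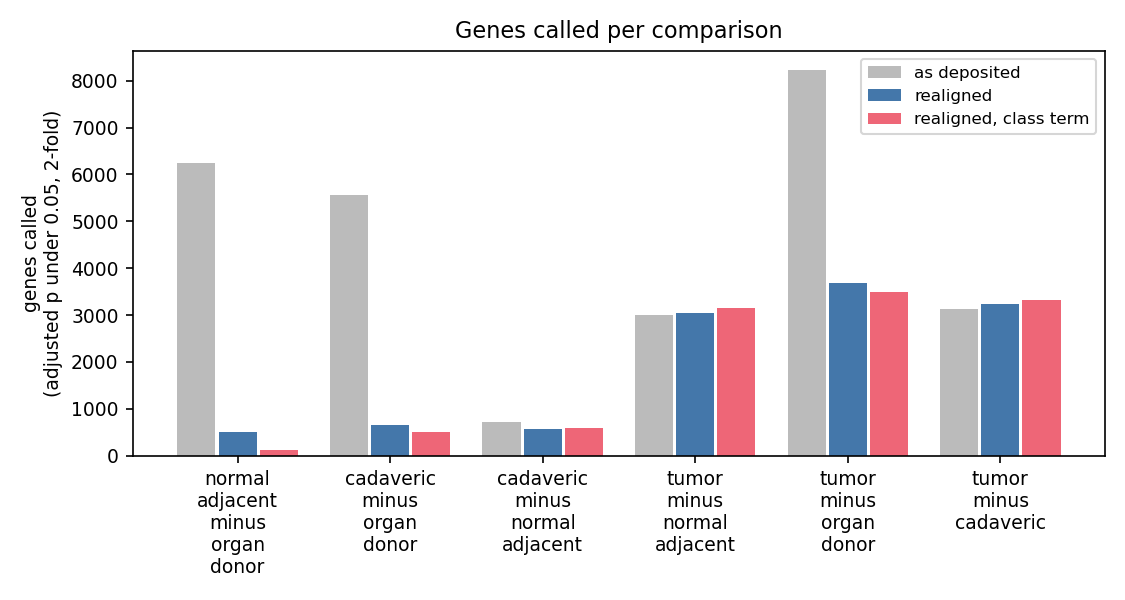
Number of genes called (vertical axis) in the 6 comparisons for the counts as deposited, the realigned counts, and the realigned counts with the library class as a term. The 3 comparisons with organ donors fall most from the deposited to the realigned counts, for example from 6235 to 513 in normal adjacent minus organ donor.

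Libraries with the same specimen number addressed how much of a difference is technical. The labels do not say what the letters mean, and they were read as repeat libraries of one specimen, which the sums per specimen rest on as well. As deposited, 5431 genes were called between letters B and A and 5419 between C and A, and none between C and B, where 137 genes had an unadjusted p below 0.05 in edgeR and DESeq2 also called 0. After realignment, 16 genes were called for B minus A, 23 for C minus A and 0 for C minus B, where 168 genes had an unadjusted p below 0.05. The offsets and the row check were set on these same libraries. Rows whose summed counts differed between A and the other letters by more than 1 on the log2 scale were left out. Few calls against A are therefore partly built in. In 1 lettered specimen, library A did not match libraries B and C. Without it, the realigned counts gave 6, 8 and 0 calls, with 622 genes at an unadjusted p below 0.05 in C minus B. In the other 9 specimens, the variance between library A and the sum of B and C was 1.14 to 1.34 times counting noise.

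Normal adjacent tissue was compared with organ donor tissue to ask whether the source of non-tumor kidney changes its expression profile. Immediate early genes, which are transcribed within minutes of a stimulus, were higher in normal adjacent tissue. FOSB (ENSG00000125740; GRCh38 chromosome 19, 45467995 to 45475179) had 158 ± 154 CPM (SD, n = 26) against 8.49 ± 10.4 CPM (n = 20), 19.1-fold higher (log2 4.26, SE 0.46, adjusted p = 3.32e-10). FOS, a component of the AP-1 transcription factor, was 8.15-fold and EGR1, a zinc finger transcription factor, 5.89-fold higher, and all 26 normal adjacent specimens lay above the organ donor median for both. Of 20 immediate early genes, 18 passed the test (19 adjusted over the list alone), all higher, with a median log2 fold change of 1.94. The organic anion transporter gene SLC22A6 had 58.3 ± 51.8 CPM against 305 ± 212 CPM and was 5.15-fold lower (adjusted p = 4.82e-06), though at log2 0.49 as deposited, on a displaced row. It was among the 11 of 20 proximal tubule genes that were lower, a list that did not pass as a whole with an estimated correlation (adjusted p = 0.257).

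The immediate early group also included DUSP1 and ZFP36, which encode a phosphatase of MAP kinases and a protein of mRNA decay, at 4.74-fold and 5.06-fold higher. DUSP2 was 10.1-fold and ARC 9.91-fold higher. Of 18 drug metabolism genes, 12 were lower (13 adjusted over the list alone), among them CYP24A1, which inactivates vitamin D (4.78-fold), and UGT1A6, a glucuronosyltransferase (4.02-fold), though not as a list with an estimated correlation (adjusted p = 0.157). Of 20 organic ion transporters, 14 were lower and 1 higher (the same numbers adjusted over the list alone), with ABCC2, an apical efflux pump, 5.49-fold lower. Of the proximal tubule genes, 11 were lower (13 lower and 1 higher adjusted over the list alone), with the sodium bicarbonate cotransporter SLC4A4 5.02-fold and the dicarboxylate transporter SLC13A3 4.89-fold lower. CYP4A11, a fatty acid hydroxylase, was 3.95-fold lower (log2 0.65 as deposited, on a displaced row). All 8 metallothionein genes were higher (8 adjusted over the list alone), with MT2A 2.36-fold and MT1F 2.15-fold higher, but with the library class as a term neither passed (log2 0.64 and 0.44, adjusted p = 0.307 and 0.479). Of 10 glucocorticoid response genes, 7 were higher (7 adjusted over the list alone), among them TSC22D3 at 3.02-fold. Of 6 cytotoxic lymphocyte genes, 5 were higher (6 adjusted over the list alone), with GNLY 3.51-fold and NKG7 3.37-fold higher. In the T cell list, 5 of 10 genes were higher (8 adjusted over the list alone), with CD3D 2.58-fold and CD8B 2.59-fold higher. With 2 technical factors both were lower (log2 -0.56 and -0.63, adjusted p = 0.723 and 0.667), CD8B was at log2 -0.42 as deposited, on a displaced row, and CD3D had an adjusted p of 0.358 with the class term. Of 3 red cell genes, 2 were higher (2 adjusted over the list alone), namely the alpha globin genes HBA2 (7.37-fold) and HBA1 (5.15-fold), which share reads with each other. Of 35 ribosomal protein genes, 25 were higher (28 adjusted over the list alone) by a median log2 of 0.39, with RPS14 1.5-fold and RPL18 1.48-fold higher. OLFM4 and ECEL1 were 7.98-fold and 7.30-fold lower, and PI15 was lower at 0.721 ± 1.19 against 5.55 ± 5.09 CPM (adjusted p = 2.38e-06), below the depth floor in normal adjacent tissue. AKR1B10 had a median of 0.773 CPM against 5.21 CPM and the mitochondrial pseudogene MTCO1P12 5.27 CPM against 11.1 CPM, and both share reads with near copies. The macrophage gene CD163 was 2.27-fold lower. With the class term GNLY (adjusted p = 0.136), NKG7 (adjusted p = 0.262), HBA1 (adjusted p = 0.113), RPS14 (adjusted p = 0.18), RPL18 (adjusted p = 0.22) and CD163 (adjusted p = 0.275) did not pass.

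The tubular injury genes HAVCR1 (6.22 ± 5.78 against 8.12 ± 4.48 CPM, adjusted p = 0.468) and LCN2 (23.9 ± 47.8 against 19.6 ± 29 CPM, adjusted p = 0.967) did not pass the test. The same held for UMOD, AQP2, NPHS1, SLC34A1, SLC22A2, VEGFA, NDUFA4L2, IL6, MT-CO1 and HSPA1A, with adjusted p from 0.0594 to 0.851; HSPA1A shares reads with a near copy. As deposited, on displaced rows, IL6 was at log2 -1.85, MT-CO1 at 2.84, NDUFA4L2 at 2.45 and SLC34A1 at -1.1, and all 4 passed. With camera, the gene set test used for the lists, 24 of 41 lists passed with a preset correlation. With an estimated correlation, 3 passed: immediate early (adjusted p = 7.24e-05), cytotoxic lymphocyte (adjusted p = 0.00772) and red cell (adjusted p = 0.00772). Those lost were, among others, drug metabolism (adjusted p = 0.157 with an estimated correlation), organic ion transporters (adjusted p = 0.179), proximal tubule (adjusted p = 0.257), metallothionein (adjusted p = 0.0612), glucocorticoid response (adjusted p = 0.179), T cell (adjusted p = 0.179) and ribosomal protein (adjusted p = 0.574). Without the libraries below 500000 counts, only the immediate early list passed with an estimated correlation (adjusted p = 0.00897).

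Of the 14013 genes tested on realigned counts, 513 were called, 287 higher and 226 lower, and 4737 had an adjusted p below 0.05 at any fold. The table as deposited gave 6235 calls, 3274 higher and 2961 lower. With the class of the libraries (displaced or not) as a term, 116 genes were called, 107 of them among the 513, and the immediate early list kept an estimated-correlation adjusted p of 8.32e-05 with 12 of 20 genes higher. Within libraries that were not displaced (26 against 3 specimens), 6 genes were called with edgeR (561 at an unadjusted p below 0.05), and within displaced libraries (2 against 18 specimens) 3 were. The fold changes of 497 of the realigned calls could be read in both classes: 93.8% had the same sign as over all libraries in those not displaced, 85.9% in displaced ones and 80.9% in both. These calls were chosen on the same specimens, so agreement of sign is partly built in, and few calls with 3 or 2 specimens in a group do not show that the differences are absent.

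Cadaveric tissue was compared with organ donor tissue for the same question. Mitochondrially encoded RNA and globin RNA were higher in cadaveric tissue. All 12 mitochondrial mRNA genes measured were higher (12 adjusted over the list alone), with a median log2 fold change of 3.11. MT-ND4, a subunit of complex I, was 13.7-fold higher (log2 3.77, SE 0.44, adjusted p = 6.99e-09) and MT-CYB 10.6-fold higher, and 19 of 20 cadaveric specimens lay above the organ donor median for both. HBA2 had 528 ± 999 CPM (SD, n = 20) against 7.32 ± 17.3 CPM (n = 20), and all 3 red cell genes were higher (3 adjusted over the list alone).

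The share of counts on mitochondrial mRNA was 40.7 ± 17.5% (SD, n = 20) in cadaveric tissue, 16 ± 5.44% (n = 20) in organ donors, 15.4 ± 6.61% (n = 26) in normal adjacent tissue and 10.6 ± 9.11% (n = 25) in tumors. Two-sided permutation tests of the 6 pairs gave an adjusted p of 2e-05 for cadaveric tissue against each other group, whose unadjusted p of 1e-05 is the smallest the 100000 resamples can give. Normal adjacent and organ donor tissue did not differ (p = 0.71, adjusted p = 0.71), and tumors were lower than both (p = 0.037 and 0.023, adjusted p = 0.044 and 0.035). Without the libraries below 500000 counts, the last 2 had an adjusted p of 0.078 and 0.061.

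**Figure D3:**
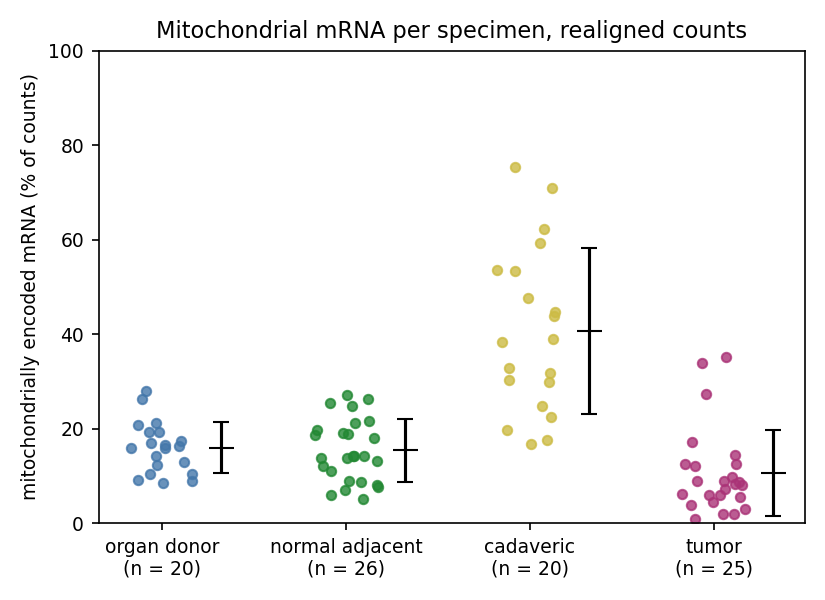
Share of counts on mitochondrially encoded mRNA (vertical axis, percent) per specimen in the 4 groups after realignment; each point is a specimen and the bars give the mean and SD. Cadaveric specimens have a mean of 40.7%, and the other groups have means from 10.6% to 16%.

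The mitochondrial ribosomal RNAs MT-RNR2 and MT-RNR1 were 18.9-fold and 13.7-fold higher in cadaveric than in organ donor tissue. The pseudogene MTCO2P12, which shares reads with MT-CO2, had a median of 4.71 CPM against 1.19 CPM. Of 20 interferon genes, 11 were higher (11 adjusted over the list alone), with IFI6 6.52-fold and ISG15 4.38-fold higher. Of 8 metallothionein genes, 5 were higher (7 adjusted over the list alone), among them MT2A at 2.00-fold and MT1F at 1.89-fold. With the class term IFI6 (adjusted p = 0.0569), MT2A (adjusted p = 0.203) and MT1F (adjusted p = 0.629) did not pass. All 4 replication histone genes, whose RNA lacks a poly(A) tail in its usual form, were higher (4 adjusted over the list alone), with HIST1H1C 3.62-fold and HIST2H2BE 3.18-fold higher. Of 35 ribosomal protein genes, 28 were higher (28 adjusted over the list alone), such as RPS28 at 1.94-fold and RPS15 at 1.75-fold. NDUFA4L2, a target of hypoxia-inducible factors, was 2.68-fold higher, and the cytotoxic genes GNLY and PRF1 were 3.32-fold and 2.70-fold higher. Of 10 macrophage genes, 8 were lower (8 adjusted over the list alone), with CD163 4.33-fold and VSIG4 3.51-fold lower. Of 20 organic ion transporters, 8 were lower (8 adjusted over the list alone), including ABCB1 at 2.14-fold and ABCC4 at 1.93-fold. PCNA, of the cell cycle list, was 1.51-fold lower, and RRM2 had 4.28 ± 4.90 against 6.82 ± 11.2 CPM (adjusted p = 0.0706). LYZ was 5.42-fold lower, and the B cell gene MS4A1 had a median of 0 against 3 CPM (adjusted p = 0.0352). ANGPTL7 (0.393 ± 0.915 against 10.9 ± 19.2 CPM, adjusted p = 0.000313), the cannabinoid receptor gene CNR1 (0.926 ± 1.56 against 6.71 ± 7.06 CPM, adjusted p = 0.000473) and PTX3 (1.15 ± 2.11 against 5.41 ± 10.6 CPM, adjusted p = 0.0088) were lower, all at means below the cadaveric depth floor, so no fold is given. FOS and EGR1, at 104 ± 108 and 79.9 ± 78.6 CPM, did not pass the test against organ donors (adjusted p = 0.618 and 0.712), nor did VEGFA, HAVCR1, IL6, LCN2, NPHS1, AQP2, UMOD, CYP4A11 and SLC22A6, with adjusted p from 0.107 to 0.976. As deposited, on displaced rows, IL6 was at log2 -1.88, CYP4A11 at 1.73 and SLC22A6 at 1.88, and all 3 passed. SLC34A1 was 2.59-fold and SLC22A2 1.91-fold lower, and HSPA1A, with a median of 0 in both groups, had an adjusted p of 0.045 (0.136 with the class term).

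With a preset correlation 24 of 41 lists passed, and with an estimated correlation the mitochondrial (adjusted p = 0.000138) and red cell (adjusted p = 1.92e-05) lists did. The estimated-correlation adjusted p was 0.526 for interferon, 0.375 for metallothionein, 0.0986 for replication histone, 0.526 for ribosomal protein, 0.375 for macrophage, 0.526 for organic ion transporters, 0.384 for cell cycle and 0.202 for cytotoxic lymphocyte genes. Of 14013 genes, 656 were called, 314 higher and 342 lower, and 5178 had an adjusted p below 0.05. As deposited, 5561 were called (3081 higher, 2480 lower, 55.4% higher; 37.7% higher with RLE size factors), and with the class term 496, of which 392 were among the 656. Within libraries that were not displaced (20 against 3 specimens) edgeR called 0 genes, with 717 at an unadjusted p below 0.05 and no other tool run, and within displaced libraries (4 against 18 specimens) it called 1444. Of 630 realigned calls read in both classes, 95.6% had the same sign in libraries not displaced, 98.1% in displaced ones and 93.8% in both, again on the specimens that gave the calls. Fold changes were lower for genes with longer transcripts (median of the longest minus that of the shortest -0.422, rank correlation -0.285), the largest such trend of the 6 comparisons. Without libraries below 500000 counts the mitochondrial list had an estimated-correlation adjusted p of 0.112, with 12 of 12 genes still higher.

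Cadaveric tissue was compared with normal adjacent tissue, the pair of non-tumor sources least affected by the displaced libraries. Mitochondrial RNA was higher and immediate early and T cell RNA lower in cadaveric tissue. All 12 mitochondrial mRNA genes were higher (12 adjusted over the list alone), with a median log2 fold change of 2.97. MT-CO1 had a median of 92800 CPM (n = 20) against 33400 CPM (n = 26). Its fitted change of 5.66-fold was larger than the difference between these medians. The share of counts on mitochondrial mRNA had medians of 38.7% and 14.2%. Of 20 immediate early genes, 18 were lower (18 adjusted over the list alone): FOSB had 2.03 ± 3.30 against 158 ± 154 CPM (83.3-fold lower, log2 -6.38, SE 0.65, adjusted p = 8.68e-11), and FOS, EGR1 and KLF4 were 6.89-fold, 6.77-fold and 3.48-fold lower in all 20 cadaveric specimens relative to the normal adjacent median. Of 10 T cell genes, 9 were lower (10 adjusted over the list alone), with CD4 2.18-fold lower and CD3D at 0.735 ± 2.02 against 5.64 ± 6.23 CPM (adjusted p = 0.000158), below the cadaveric depth floor.

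The mitochondrial genes MT-ND4 and MT-ND4L were 11.2-fold and 8.90-fold higher, and the tRNA gene MT-TV was at 6.09 ± 7.48 against 0.816 ± 2.09 CPM (adjusted p = 1.86e-06), below the depth floor in normal adjacent tissue. The pseudogenes MTCO2P12 and MTCO1P12 had medians of 4.71 and 21.3 CPM against 0.457 and 5.27 CPM. All 3 red cell genes were higher (3 adjusted over the list alone), with HBA1 14.1-fold and HBA2 10.4-fold higher. Of 9 oxidative stress genes, 7 were higher (8 adjusted over the list alone), among them HMOX1, the heme oxygenase, at 4.73-fold, and AKR1B10, whose median was 0.582 against 0.773 CPM although its fitted change was positive. GPX2, a glutathione peroxidase, was 14-fold higher. Of 18 hypoxia genes, 9 were higher (11 adjusted over the list alone), with ANGPTL4 6.70-fold and LDHA 1.88-fold higher. S100A8 and S100A9, the calprotectin subunits in the neutrophil list, were 10.2-fold and 5.38-fold higher, and 2 of 5 members of that list passed (2 higher and 1 lower adjusted over the list alone). In the tubular injury and acute phase list, 4 of 18 genes were higher (5 adjusted over the list alone), and the fibrinogen genes FGA and FGG had medians of 4.70 and 0.465 CPM against 0.699 and 0.360 CPM. SLC22A6 and CYP4A11 were 2.89-fold and 2.42-fold higher, SLC22A2 1.67-fold lower, and NDUFA4L2 1.94-fold higher by the fit although its median was 9.9 against 11 CPM. VEGFA, HAVCR1, SLC34A1, IL6, LCN2, NPHS1, AQP2, UMOD, CD163 and HSPA1A did not pass, with adjusted p from 0.0956 to 0.98. Of 17 extracellular matrix genes, 7 were lower (10 adjusted over the list alone), with THBS1 2.96-fold and TNC 2.23-fold lower, and of 13 fibroblast and pericyte genes (RGS5 has 2 Ensembl IDs) 7 were lower (7 adjusted over the list alone), with LUM 2.90-fold and THY1 2.32-fold lower. The granzyme gene GZMK (0.285 ± 0.577 against 7.53 ± 7.98 CPM, adjusted p = 1.81e-05), the IgE receptor gene FCER1A (0.505 ± 1.28 against 5.46 ± 4.29 CPM, adjusted p = 0.000193) and EGR2 (1.06 ± 1.82 against 11.7 ± 12.8 CPM, adjusted p = 6.11e-05) were lower, at cadaveric means below the depth floor, so no fold is given.

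With a preset correlation 19 of 41 lists passed. With an estimated correlation the mitochondrial (adjusted p = 2.45e-05), immediate early (adjusted p = 0.00408), red cell (adjusted p = 0.012) and T cell (adjusted p = 0.0275) lists did, and the first 2 did so without libraries below 500000 counts (adjusted p = 0.0235 each). The estimated-correlation adjusted p was 0.231 for oxidative stress, 0.524 for hypoxia, 0.0824 for neutrophil, 0.475 for tubular injury, 0.431 for extracellular matrix and 0.414 for fibroblast genes. Of 14013 genes, 577 were called, 206 higher and 371 lower, and 2661 had an adjusted p below 0.05. As deposited, 723 were called, 430 higher and 293 lower, and 388 of them were among the 577 in the same direction.

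Tumors were compared with normal adjacent tissue, their usual reference. The series text calls the tumors matching, so both groups may hold tissue of the same patients. No label pairs them, and the tests treated the specimens as independent. Genes induced by hypoxia-inducible factors and known from clear cell renal carcinoma were higher in tumors, and genes of the distal nephron and glomerulus were lower. CA9 (ENSG00000107159; GRCh38 chromosome 9, 35673856 to 35681159), a carbonic anhydrase, had 224 ± 161 CPM (SD, n = 25) against 0.331 ± 0.417 CPM (n = 26), below the depth floor (adjusted p = 1.08e-30), and NDUFA4L2 had 1300 ± 922 against 12.6 ± 9.12 CPM (log2 6.83, SE 0.38, adjusted p = 6.19e-29). All 13 genes of the clear cell carcinoma list were higher (13 adjusted over the list alone) and 17 of 19 hypoxia genes were (17 adjusted over the list alone). All 10 thick ascending limb genes and all 10 principal cell genes were lower (10 and 10 adjusted over the list alone), with median log2 fold changes of -5.78 and -3.55. UMOD (GRCh38 chromosome 16, 20333052 to 20356301), which encodes uromodulin, had a median of 0.292 CPM in tumors and 4520 CPM in normal adjacent tissue, and the water channel gene AQP2 0 and 1240 CPM.

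VEGFA, the vascular endothelial growth factor, was 3320 ± 2470 CPM against 396 ± 185 CPM, and the lipoprotein receptor gene SCARB1 281 ± 169 against 14.6 ± 4.94 CPM. SLC6A3, a dopamine transporter, had 224 ± 225 against 0.160 ± 0.291 CPM and FABP6, a bile acid binding protein, 27 ± 32.7 against 0.0616 ± 0.141 CPM. LINC00462 (12.3 ± 13.3 CPM) and the antisense gene TTC21B-AS1 (17.9 ± 23.9 CPM) were below the depth floor in normal adjacent tissue, and for an antisense gene reads of the partner gene cannot be ruled out. Of 20 cell cycle genes, 19 were higher (19 adjusted over the list alone), with UBE2C at log2 3.13 and MCM5 at log2 1.21. Immune genes that passed the gene test were 9 of 9 cytotoxic lymphocyte genes (9 adjusted over the list alone; NKG7 log2 2.89, PRF1 2.62), 11 of 11 macrophage genes (11; FCGR3A 2.93, CD68 2.45) and 10 of 11 T cell genes (10; CD8A 2.97, CD4 1.46), all higher. With an estimated correlation none of these 3 lists passed (adjusted p = 0.0539, 0.191 and 0.225). The injury marker HAVCR1 was higher by log2 1.5. Of 11 podocyte genes, 10 were lower and 1 higher (the same adjusted over the list alone), with NPHS1, the slit diaphragm gene, at log2 -6.75. NTNG1 was at 0.145 ± 0.536 against 21.3 ± 15.7 CPM and the channel gene SCNN1G at 0.557 ± 1.5 against 196 ± 114 CPM, both below the depth floor in tumors, and the channel gene KCNJ1 fell by 7.45 on the log2 scale. KNG1, the kininogen gene, had a median of 0.0999 against 565 CPM, and MUC15 and GP2 were below the depth floor in tumors, against 24.2 ± 19.7 and 57.5 ± 50.5 CPM. SLC34A1, LCN2, EGR1 and FOS were lower by log2 -2.41, -3.01, -2.10 and -1.04, and CD163 higher by 1.23. SLC22A2, SLC22A6, CYP4A11, IL6, MT-CO1 and HSPA1A did not pass, with adjusted p from 0.39 to 0.992. The tumor medians of SLC22A6 and CYP4A11 were nevertheless 4.4 and 16.7 CPM against 39.8 and 71.3 CPM, and limma-voom on realigned counts gave log2 -2.2 and -1.23, both with an adjusted p below 0.05, so for these 2 genes the result depends on the test.

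The intercalated cell list was lower by camera (adjusted p = 9.21e-22, and 0.0015 with an estimated correlation), although only 2 of its 9 genes passed the gene test (1 adjusted over the list alone), SLC26A4 at log2 -2.81 and SLC26A7 at -1.30. With an estimated correlation 7 of the 23 lists that passed with the preset one did so: principal cell and thick ascending limb (adjusted p = 0.000928 each), intercalated cell, clear cell carcinoma (adjusted p = 0.00395), podocyte (adjusted p = 0.0124), cell cycle (adjusted p = 0.0321) and hypoxia (adjusted p = 0.0383). Of 14472 genes, 3047 were called, 1652 higher and 1395 lower, and 2996 as deposited, 1688 higher and 1308 lower, of which 2581 were among the 3047. With RLE size factors in place of TMM, 89.6% of the calls as deposited were higher in tumors, against 56.3% with TMM, and the median log2 fold change over all genes moved from 0.08 to 0.82.

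**Figure D4:**
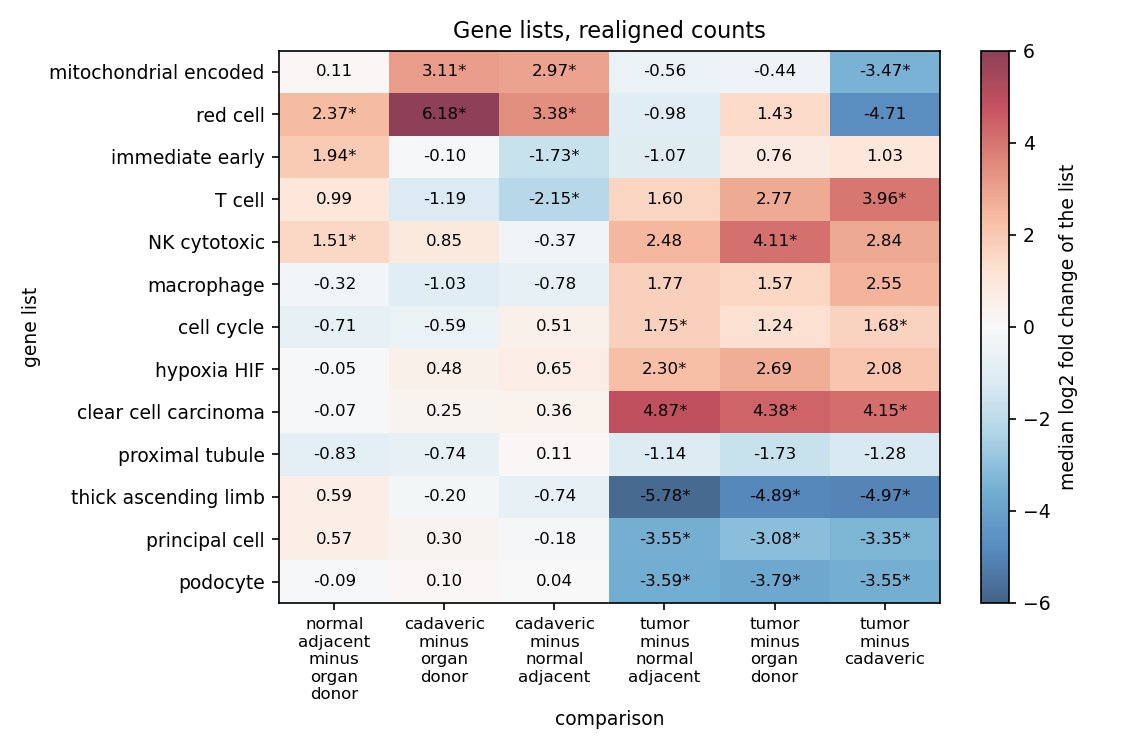
Median log2 fold change of 13 gene lists (rows) in the 6 comparisons (columns) on realigned counts, as color and printed value; an asterisk marks an adjusted p below 0.05 in camera with an estimated correlation. Mitochondrial genes have medians of 3.11 and 2.97 in the 2 comparisons of cadaveric tissue with the other non-tumor tissues, and the thick ascending limb list is lowest in the tumor comparisons.

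Tumors were also compared with organ donor tissue. The same groups led: NDUFA4L2 was at 8.29 ± 3.70 CPM (n = 20) in organ donors (log2 7.31, SE 0.43, adjusted p = 3.64e-27), and CA9 and SLC6A3 were at 0.141 ± 0.181 and 0.0424 ± 0.0784 CPM, below the depth floor (adjusted p = 7.26e-32 and 3.97e-27). All 13 clear cell carcinoma genes (13 adjusted over the list alone) and 17 of 19 hypoxia genes (17) were higher, and 1 hypoxia gene was lower. All 10 thick ascending limb and all 10 principal cell genes were lower (10 and 10 adjusted over the list alone), and 10 of 11 podocyte genes were (10). UMOD had a median of 1020 CPM in organ donors and 0.292 CPM in tumors, SLC12A1, the sodium potassium chloride cotransporter, 288 and 0.274 CPM, and OLFM4 98.2 and 0 CPM.

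All 9 cytotoxic lymphocyte genes were higher (9 adjusted over the list alone), with GZMH at log2 4.66 and GNLY at 4.14, and 10 of 11 T cell genes were (11), with CD8A at 4.20 and CD4 at 1.90. Of 20 proximal tubule genes, 14 were lower (14 adjusted over the list alone), among them SLC22A8 at log2 -5.51 and the glucose transporter gene SLC5A2 at -3.67, and SLC22A6, CYP4A11 and SLC34A1 were at -2.36, -2.04 and -3.36 (the first 2 at 0.53 and 0.6 as deposited, on displaced rows). Of 20 cell cycle genes, 15 were higher (17 adjusted over the list alone), with MCM5 at log2 1.60 and UBE2C at 2.35. FOS was higher by log2 1.98 and HAVCR1 by 1.15, LCN2 lower by -2.92, and EGR1 (0.45), SLC22A2 (-0.05), IL6 (0.22), CD163 (0.07), MT-CO1 (-0.43) and HSPA1A (0.43) did not pass. As deposited IL6 was at -1.81 and MT-CO1 at 2.6, and DESeq2 on realigned counts without libraries below 500000 counts gave -1.37 for IL6, all with an adjusted p below 0.05. With an estimated correlation 6 of 27 lists passed, at an adjusted p of 0.0054 for clear cell carcinoma, cytotoxic lymphocyte, principal cell and thick ascending limb genes, 0.0049 for intercalated cell genes, of which 2 of 9 passed the gene test (2 adjusted over the list alone), and 0.0145 for podocyte genes. The hypoxia (adjusted p = 0.0561), T cell (adjusted p = 0.0886), proximal tubule (adjusted p = 0.223) and cell cycle (adjusted p = 0.223) lists did not. Of 14472 genes, 3676 were called, 2038 higher and 1638 lower, against 8229 as deposited, 4267 higher and 3962 lower. With the class term 3499 were called, 3183 of them among the 3676, and within libraries that were not displaced (25 against 3 specimens) 1896.

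Tumors were finally compared with cadaveric tissue. Tumors again had higher CA9 (cadaveric 0.323 ± 0.875 CPM, n = 20, below the depth floor; adjusted p = 3.23e-24), SCARB1 (log2 4.15, SE 0.27), NDUFA4L2 (5.91) and VEGFA (3.04), and lower UMOD and AQP2, whose cadaveric medians were 3110 and 990 CPM. In this comparison the mitochondrial genes were lower in tumors as well: 12 of 12 passed (12 adjusted over the list alone), with MT-CO2 at log2 -4.04 and MT-ND4 at -4.01. T cell genes were higher, 11 of 11 (11 adjusted over the list alone), with CD8A at log2 4.76 and CD4 at 2.60.

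All 13 clear cell carcinoma genes and 16 of 19 hypoxia genes were higher (13 and 16 adjusted over the list alone). Of 11 macrophage genes, 10 were higher (10 adjusted over the list alone), with C1QC at log2 3.75 and FCGR3A at 3.51, and of 20 cell cycle genes 18 were (18), with MCM5 at 1.68 and MCM2 at 1.63. FABP6 and the chitinase gene CHIT1 had medians above those of cadaveric tissue, where both were below the depth floor, and TTC21B-AS1 was at 0 in all cadaveric specimens, so no fold is given. All 10 thick ascending limb, 9 of 10 principal cell and 10 of 11 podocyte genes were lower (10, 9 and 10 adjusted over the list alone), with KCNJ1 at log2 -7.22 and NPHS1 at -6.73. SCNN1G (122 ± 89.1 CPM) and NTNG1 (23.9 ± 22.7 CPM) in cadaveric tissue also exceeded the tumor means, which lay below the depth floor. CRYAA and SOST had cadaveric medians of 6.27 and 2.41 CPM and tumor medians of 0. FOS, HAVCR1, CD163 and SLC22A2 were higher by log2 1.75, 1.69, 2.19 and 0.90, and LCN2, SLC34A1, SLC22A6, CYP4A11 and MT-CO1 lower by -2.93, -1.98, -1.51, -1.31 and -2.65. With RLE size factors CYP4A11 was at 0.24, SLC22A6 at -0.74 and SLC34A1 at -0.44, none with an adjusted p below 0.05, so these 3 falls depend on the scaling. That scaling kept the near-empty libraries and moved the median log2 fold change of all genes to 1.588. EGR1, IL6 and HSPA1A did not pass (adjusted p = 0.161, 0.561 and 0.0593). With an estimated correlation 8 of 23 lists passed: principal cell (adjusted p = 0.0024), thick ascending limb (adjusted p = 0.00303), intercalated cell (adjusted p = 0.00306), podocyte (adjusted p = 0.0139), clear cell carcinoma and mitochondrial (adjusted p = 0.0303 each), T cell (adjusted p = 0.0389) and cell cycle (adjusted p = 0.0405). Hypoxia (adjusted p = 0.172) and macrophage (adjusted p = 0.129) genes did not. Without libraries below 500000 counts, 7 lists passed with an estimated correlation against normal adjacent tissue, 2 against organ donors and 3 against cadaveric tissue, and the mitochondrial list did not in the last (adjusted p = 0.135). In the intercalated cell list the median log2 fold change was 0.10, not negative, while camera gave a lower rank, and 1 of 9 genes passed (0 adjusted over the list alone). Of 14472 genes, 3240 were called, 1838 higher and 1402 lower, against 3130 as deposited, 1710 higher and 1420 lower. With RLE size factors 93.4% of the calls as deposited were higher, against 54.6% with TMM.

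How far the list of tumor genes depends on the reference tissue was read from the overlap of the 3 tumor comparisons. On realigned counts, 1233 genes were higher and 1000 lower in tumors against all 3 references, including CA9, NDUFA4L2 and SCARB1 among the higher and UMOD, AQP2 and NPHS1 among the lower, out of 4578 called against any. Another 258 were called only against normal adjacent, 754 only against organ donor and 417 only against cadaveric tissue. With the class term these numbers were 253, 524 and 487, and within libraries that were not displaced (3 organ donor specimens) 614, 117 and 715, so their order depends on the setting and on power. As deposited, 988 were higher and 798 lower against all 3, out of 9271, and 5323 were called only against organ donors. Log2 fold changes against normal adjacent and organ donor tissue correlated across genes at r = 0.926 after realignment and 0.406 as deposited (genes are not independent replicates), with 1405 higher and 1153 lower genes shared, against 232.6 and 157.9 for independent lists. The tumors are common to both comparisons: simulated counts with no effect gave r = 0.535 and a covariance of 0.0387 with 0 shared calls, and with limma-trend on realigned counts the covariance was 1.30 with all tumors and 1.25 (r = 0.855, median of 20 random divisions) when each comparison used different tumors. For normal adjacent and cadaveric references 1354 higher and 1104 lower genes were shared (r = 0.905, independent lists 209.8 and 135.1), and for organ donor and cadaveric references 1478 and 1114 (r = 0.904, independent lists 258.8 and 158.7). Simulation gave r = 0.456 and 0.471 for these pairs, and different tumors in each comparison gave r = 0.831 and 0.814.

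Normal adjacent and cadaveric tissue shared 80 higher and 61 lower genes against organ donors on realigned counts, with 14 in opposite directions, against 6.4 and 5.5 for independent lists. As deposited the numbers were 2941, 2170 and 12, and with the class term 14, 13 and 1. The correlation across genes was r = 0.473 (covariance 0.118) on realigned counts, while simulated counts with no effect gave 0.404 (covariance 0.0218), and with limma-trend it was 0.506 (covariance 0.139) with all donors and 0.408 (covariance 0.118) when each comparison used different donors. Most donors have only displaced libraries, so different donors still share the library class, which the simulation left out. Fold changes of both comparisons also rose with GC content (r = 0.395 and 0.447). These values therefore cannot tell a shared tissue change from a shared class difference.

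Specimens differed in how far they lay from their group's center. On realigned counts, the mean distance over the 2000 most variable genes was 48.6 ± 6.62 (SD, n = 20) in organ donors, 65.8 ± 23.5 (n = 26) in normal adjacent, 87.7 ± 38.6 (n = 25) in tumor and 95.1 ± 37.5 (n = 20) in cadaveric specimens, in log2 CPM units. Two-sided permutation tests over the 6 pairs gave p = 1e-05 (the smallest possible) for cadaveric and tumor against organ donor specimens (adjusted p = 3e-05), 3e-04 for normal adjacent against organ donor (adjusted p = 6e-04), 0.00052 for normal adjacent against cadaveric (adjusted p = 0.00078), 0.0093 for tumor against normal adjacent (adjusted p = 0.011) and 0.53 for tumor against cadaveric (adjusted p = 0.53). As deposited, only normal adjacent against cadaveric passed (p = 0.0039, adjusted p = 0.023), and organ donor specimens were at 74.3 ± 73.4. Organ donor libraries were also the deepest, with a median total of 19505564.5 counts.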

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

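Settings named with realignment, library class, near-empty libraries (below 500000 counts), thinning, GC content, row checks or rows with no offset were chosen after the data were examined, and so were the tests named "realigned". All other settings were fixed before. Settings thinned to at most 1000000 counts also leave out the near-empty libraries. Of the gene, list, letter, spread and overlap counts, 136 alternative values kept their side of the threshold or stayed within 1.5 times. A larger number of them moved further, changed side or were reversed. Where a value moved, the cause was not tested unless the construction shows it.

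The 3 comparisons with organ donors are given in the order normal adjacent, cadaveric and tumor minus organ donor. Realignment gave 513, 656 and 3676 calls, against 6235, 5561 and 8229 as deposited. The rows with no offset gave 316, 339 and 2232 and test fewer genes. With the class term there were 116, 496 and 3499. Libraries not displaced gave 6, 0 and 1896 (few organ donors), and displaced libraries 3, 1444 and 4727 (few of the other group). Without near-empty libraries, realigned counts gave 567, 722 and 3778 with edgeR and 575, 742 and 3859 with DESeq2. Without the specimen that does not match they gave 497, 662 and 3637, with letter A only 445, 587 and 3562, thinned to at most 1000000 counts 293, 333 and 2601, with limma-voom 547, 701 and 3754, with RLE 503, 1201 and 6630, with 2 technical factors 163, 462 and 2558, with the GC trend removed 475, 485 and 3395, and with the first row check 555, 690 and 3767. As deposited, 2 technical factors gave 2852, 3640 and 5740 (95.2%, 94.6% and 85.2% higher, against 51.9% in the last without them). Without the genes that differ between letters, the 3 gave 1261, 1241 and 3347 (75.9%, 72% and 69.3% higher). No filter gave 12376 for normal adjacent and 14224 for tumor.

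In cadaveric minus normal adjacent (723 as deposited), limma-voom gave 2151, no filter 1812, letter A only 444, the 2 groups alone 416, and the table without genes that differ between letters 401. Rows with no offset gave 352, displaced libraries 296, realigned and thinned counts 323, realigned limma-voom 332 and realigned counts with 2 technical factors 353. In tumor minus normal adjacent (2996), DESeq2 gave 6073, RLE 6310, no filter 5484, rows with no offset 1841 and realigned RLE 6468. In tumor minus cadaveric (3130) the same settings gave 8065, 8247, 5013, 1931 and 11736.

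RLE size factors moved the median log2 fold change of all genes by over 0.1, which changes the split of calls. As deposited the medians were -0.45 and -0.56 for normal adjacent and cadaveric minus organ donor, and 0.82 and 1.02 for tumor minus normal adjacent and cadaveric. After realignment they were 0.87, 0.82 and 1.59 for tumor minus normal adjacent, organ donor and cadaveric, with 89.5%, 88.7% and 96.6% of calls higher, and -0.10, -0.33 and -0.20 for normal adjacent minus organ donor, cadaveric minus organ donor and cadaveric minus normal adjacent, with 38%, 11% and 18.4% higher (55.9%, 47.9% and 35.7% with TMM). Without near-empty libraries, DESeq2, which uses the same size factors, gave medians within 0.1 of 0. This changes the tool and the libraries together. As deposited, with all libraries, DESeq2 and edgeR with RLE gave similar medians (0.821 and 0.819 for tumor minus normal adjacent, 0.985 and 1.016 for tumor minus cadaveric). These values argue against the tool as the source of the shift. The RLE fits kept a cadaveric library of 170 counts with 77 genes detected, so few genes had counts in every specimen. Its share in the shift was not tested. Gene lists were not run with RLE. A list median near the size of the shift, such as -0.58 of intercalated cell genes in tumor minus normal adjacent or 0.43 of ribosomal protein genes in cadaveric minus organ donor, has a direction only relative to the TMM scaling. With limma-voom as deposited 40.1% and 35.3% of the tumor calls against normal adjacent and cadaveric tissue were higher.

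Between letters, no filter gave 8524 (B minus A) and 8337 (C minus A) calls. Realignment left 16 and 23, and 6 and 8 without the specimen that does not match. This fall is partly built in, since the offsets and the row check were set on these libraries.

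The ratio of spread of cadaveric over organ donor specimens (1.46) had an unadjusted p below 0.05 with all genes (1.97), realigned (1.96), without near-empty libraries (1.72) and thinned (1.4), and was reversed with letter A only (0.782). Normal adjacent over organ donor (0.836) was reversed with all genes (1.06), realigned (1.35), without near-empty libraries (1.25) and thinned (1.12), and had such a p with letter A only (0.533). Tumor over organ donor (1.15) had such a p realigned (1.8), without near-empty libraries (1.61) and thinned (1.49) and was reversed with letter A only (0.736). Tumor over cadaveric was reversed when thinned (1.06). Tumor over normal adjacent (1.38) had such a p with all genes (1.45, p = 0.042), letter A only (1.38), realigned (1.33), without near-empty libraries (1.29) and thinned (1.33). Adjusted over the 6 pairs, all of these p values stayed below 0.05 except that of tumor over normal adjacent with all genes (adjusted p = 0.084). With fewer of the most variable genes, normal adjacent over cadaveric had p = 0.01 and an adjusted p of 0.06. Thinning to the smallest total (170 counts) was not run, since it left no gene.

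Lists passing camera with an estimated correlation as deposited numbered 0, 0, 4, 8, 0 and 8 (normal adjacent and cadaveric minus organ donor, cadaveric minus normal adjacent, tumor minus normal adjacent, organ donor and cadaveric). Realigned, they numbered 3, 2, 4, 7, 6 and 8, with the class term 1, 3, 5, 7, 6 and 8, and without near-empty libraries 1, 1, 2, 7, 2 and 3. With the preset correlation the comparisons with organ donors had 24, 24 and 27 lists realigned, 21, 26 and 28 with the class term and 20, 17 and 23 without near-empty libraries.

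Tumor genes shared against normal adjacent and organ donor, normal adjacent and cadaveric, and organ donor and cadaveric tissue numbered 4701, 4474 and 4685 by adjusted p alone and 707, 781 and 984 at 4-fold, as deposited, and 6792, 6106 and 6066, and 847, 835 and 990, realigned. The change shared by both tissues against organ donors fell from 5111 genes to 141 realigned, 27 with the class term and 0 in libraries not displaced, where edgeR called few genes in either comparison.

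Of the named genes, 18 values were reversed. On the table as deposited these were, in normal adjacent minus organ donor, SLC22A6 (0.49), CD8B (-0.42), IL6 (-1.85), CYP4A11 (0.65) and MT-CO1 (2.84), in cadaveric minus organ donor CYP4A11 (1.73) and SLC22A6 (1.88), and in tumor minus organ donor IL6 (-1.81), CYP4A11 (0.6), SLC22A6 (0.53) and MT-CO1 (2.6), all on displaced rows. With 2 technical factors CD3D (-0.56) and CD8B (-0.63) were reversed in normal adjacent minus organ donor. Limma-voom reversed SLC22A6 in tumor minus normal adjacent (-2.2) and KIT in tumor minus cadaveric (-1.74), DESeq2 without near-empty libraries IL6 in tumor minus organ donor (-1.37) and KIT (-1.85), and RLE CYP4A11 in tumor minus cadaveric (0.24). Of the others, 68 were weaker in libraries not displaced, 31 with 2 technical factors, 18 with limma-voom and 13 with the class term.

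No paired analysis was possible because the labels do not pair tumors with adjacent tissue, although the series text calls the tumors matching. The gene, mitochondrial share and spread tests between these groups therefore treat specimens as independent that may share a patient. Depth limits the floor to 1.39 CPM in cadaveric tissue against 0.15 in organ donors.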

Other observations

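All tests in this part were chosen after the results were seen, except the one on transcript length, which was fixed before its result was seen.

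In lists not described above, the endothelium list had 7 and 8 of 13 genes higher in normal adjacent and cadaveric tissue than in organ donors (7 and 8 adjusted over the list alone), with an adjusted p of 0.437 and 0.526 with an estimated correlation. Heat shock genes had 4 of 13 members higher in cadaveric than in organ donor tissue (2 adjusted over the list alone; adjusted p = 0.673 with an estimated correlation). In tumors, 13 of 15 glycolysis genes were higher and 1 lower than in normal adjacent tissue (13 and 1 adjusted over the list alone; adjusted p = 0.555 with an estimated correlation), and 19 of 20 interferon genes were higher than in organ donors (19 adjusted over the list alone; adjusted p = 0.381 with an estimated correlation).

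Counts of mitochondrial genes stood on the rows of other genes in 37 libraries. Nuclear copies of mitochondrial sequence were searched for in these rows: 0 of 11 carried such sequence. The tissue source was excluded as the cause, since all 10 lettered specimens hold libraries of both kinds. Rows displaced in some libraries fit, because moving the counts by the found offsets raised the median correlation with the other libraries from 0.174 to 0.9. The offsets were chosen for best agreement among the lettered libraries, so for those the rise is built in. The displaced organ donor libraries without a letter were not used to find them, and every displaced library rose by at least 0.66. How the displacement arose was not tested.

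Calls between normal adjacent and organ donor tissue overlapped with the class of the libraries, since organ donor specimens were mostly displaced ones. Of the 513 realigned calls, 107 stayed with the class term, which takes the class difference as the same in lettered specimens and organ donors. Between the displaced and the other organ donor libraries, summed per specimen (18 against 3), 256 genes were called. The lettered organ donor specimen is in both sets, so the sets are not independent. Across the genes compared, the fold changes of that contrast correlated with those between letters B and A at r = 0.128, and with GC content at r = -0.494, against 0.011 for the letters. The offsets and the row check had already narrowed the differences between letters, to a median absolute log2 fold change of 0.051. Low correlations with the letters are therefore partly built in and cannot decide whether the class difference is alike in both. All 513 calls, those 107 included, cannot be told apart from a difference between library classes, because the better-filled class has only 3 specimens in its smaller group. Log2 fold changes rose with GC content across genes (r = 0.395, genes are not independent replicates), while within library classes r was -0.188 (not displaced) and 0.078 (displaced), with 3 and 2 specimens in the smaller group. Of the 513 calls, 386 stayed once each specimen's own trend against GC content was removed. These trends may account for the other calls but not for most. A biological difference between sources stays open and untested.

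Mitochondrial genes were higher in cadaveric than in normal adjacent tissue. Near-empty libraries were tested by leaving out those below 500000 counts, after which the median log2 fold change of the list was 3.182. Depth was tested by also thinning specimens to at most 1000000 counts, after which it was 3.218 (12 genes, from 2.69 to 3.76), so neither is the whole cause. RNA fragmentation was read from transcript length: the median log2 fold change of the genes with the longest transcripts minus that of the genes with the shortest was -0.254, between the bounds set in advance for either answer, so the test could not decide. Against organ donors it was -0.422, also between these bounds. A consequence of the time after death or of the way the tissue was obtained may underlie the rise, and the data here cannot separate these.

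In each of the 12 combinations of fit and groups, 100 splits of the specimens were drawn, the real one included. Only the real one gave as many genes with limma-trend, so a random division of the specimens is an unlikely source of the calls. In comparisons with organ donors the groups nearly coincide with the library class, so the splits cannot separate source from class. As deposited the real splits gave 6600, 8184, 445, 2746, 9407 and 1700 calls (normal adjacent and cadaveric minus organ donor, cadaveric minus normal adjacent, tumor minus normal adjacent, organ donor and cadaveric), against at most 4427, 1597, 2, 1, 4147 and 12 in the others. Such high counts in other splits point to a structure of the samples, the displaced libraries. Realigned, the real splits gave 551, 1883, 491, 2768, 4155 and 1737, against at most 0, 1, 2, 2, 0 and 63.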
